A study of Mus musculus with 61 samples.

How the data were processed

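The study measured RNA from sorted nuclei of the mouse nucleus accumbens, the ventral part of the striatum. Per the labels' protocols, male mice carried a Cre driver for the dopamine receptor D1 or D2 gene and a Cre-dependent green fluorescent protein fused to a ribosomal protein. Nuclei were isolated from frozen tissue punches by fluorescence-activated sorting, RNA was purified with a microprep kit, and libraries were made with a stranded total RNA kit for very small inputs. Daily saline or morphine was given over 15 days, followed by 30 days in the home cage, and the mice were killed 1 h after a challenge with either, per the labels' protocols. A group name gives the repeated treatment first and the challenge second, so that SM stands for repeated saline and a morphine challenge. The labels' protocols list doses of 20 and 10 mg/kg without assigning them, and mention a cohort of another drug in the same passage. Which dose each mouse received is therefore not known here.

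Per the submitters' processing notes, the authors counted reads per gene with featureCounts on the genome build mm10 and used DESeq2. The aligner, the annotation release, the tool versions and the strand setting are not given in the sources used here. The authors deposited raw counts per gene, and the counts of all 61 libraries were used. The authors also deposited FPKM values, and these served to recover the gene length behind each value. For 54281 of 54281 identifiers with a length, that length equalled the whole gene span, introns included, in the GENCODE release M21, within a relative tolerance of 1e-06. Of the 55401 identifiers in the count table, 54349 matched that release with their version and 55141 without it, and 260 had no symbol. Coordinates are on mm10 from that release. Because the strand setting is not given, values of genes that overlap or lie antisense to another gene are uncertain.

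Counts were modelled with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and two-sided tests. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The 4 treatments of each cell type were fitted together, with 41083 genes tested in 32 D1 libraries and 41125 in 29 D2 libraries. Comparisons of the 2 cell types came from a joint fit of 42870 genes in 61 libraries. By chance, about 2054 genes in D1, 2056 in D2 and 2144 in the joint fit would have an unadjusted p under 0.05. Counts under these, as in all D1 comparisons with all libraries, are no sign of a change. The common biological coefficient of variation was 0.28 in D1, 0.154 in D2 and 0.231 jointly. Within each cell type, SM, MS and MM were compared with SS, MM with MS and with SM, and the response to the challenge was compared between histories as an interaction. Across cell types, D2 was compared with D1 in SS, and each difference from SS was compared between the cell types.

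Fixed lists of genes, 24 in number with 466 of 467 members in the file, were tested with camera in limma 3.58.1 on log2 CPM (counts scaled to a common library size) with a prior count of 2. Camera asks whether the genes of a list moved further in one direction than other genes, here two-sided with a preset inter-gene correlation of 0.01, and p values were adjusted over the 24 lists. It was repeated with the correlation estimated from the data. List medians are differences of these log2 CPM values, while the numbers of members higher or lower are signs of the edgeR fold changes. Both carry the TMM scaling. Fold changes of single genes are edgeR log2 values with their standard error (SE), and group means are TMM-scaled CPM with the standard deviation (SD) over libraries, unless named as unscaled CPM. Means of a list per library were compared with exact two-sided permutation tests over all regroupings of the libraries, and between cell types with permutation tests of 100000 draws.

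Apart from what is named below as added, the comparisons, lists, tests and thresholds were chosen before the data were examined. So was the rule for named genes. It leaves out gene models named Gm with digits, names ending in Rik or -ps, and names starting with mt-, Rpl or Rps. Among called genes with a mean of at least 1 log2 CPM it takes the 10 with the smallest p in each direction. Where fewer than 5 genes were called it adds those with the smallest p until 5, which are said not to pass. It adds called list members, up to 4 members with the smallest p from each list called by camera, and in comparisons against SS the fixed genes Fos, Arc, Fkbp5, Sgk1, Oprm1, Pdyn, Penk, Drd1, Drd2, Adora2a and Tac1. Where a mitochondrial, ribosomal or Gm gene is named below, it was chosen after its values were seen.

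A background level was measured after the data were seen. In each library, the counts over 1435 olfactory and vomeronasal receptor genes, which are not expected to be transcribed in the striatum, were summed and divided by their length and by the total count. That density times the length of all genes, over the total, gives a background share. Analyses with the log2 density as a covariate, with it and only genes at least 2 times background, and without D1 SS replicate 1 were added after seeing the data. So were differences of list means without the library that moved each furthest. The permutation tests of list means between cell types, run only for the immediate early and the mitochondrially encoded genes, were also added then. Alternatives planned before were the DESeq2 1.42.0 Wald test, DESeq2 size factors in edgeR, no filter on low counts, limma voomWithQualityWeights, 2 surrogate variables from sva 3.50.0, the replicate number as a replicate block, one fit over all 61 libraries, a fit of the contrasted groups alone, and a minimum of 5 log2 CPM for correlations across genes.

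The models were tested on simulated data built with the spread of each gene in these libraries. Genes were drawn independently, without the variation that libraries share across genes, such as background. Only genes with a mean above 1 log2 CPM were altered. The recovery rates hold for those conditions and need not hold for the real libraries. With edgeR, a 2-fold change was recovered for 70% of altered genes in D1 MM against SS, 92% in D2 MM against SS and 82% in D2 against D1. A 1.5-fold change was recovered for 24%, 78% and 48%, and a 1.2-fold change for 2%, 6% and 0%. A list raised 1.2-fold had a camera adjusted p of 0.227 in D1, 3.72e-07 in D2 and 0.0105 across cell types, and of 0.317, 0.000162 and 0.0528 with an estimated correlation. Errors over libraries rather than counting intervals are given, since PCR copies are not independent molecules. In a check for duplicates within groups, no pair differed by less than counting noise (lowest chi-squared per degree of freedom 1.72). Sequence reads were not analysed here.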

Results

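RNA of sorted nuclei was measured in 61 libraries of the mouse nucleus accumbens, 32 from mice with the D1 driver and 29 from mice with the D2 driver. These drivers mark the 2 main classes of striatal projection neuron. In D1 there were 8 SS, 8 SM, 9 MS and 7 MM libraries, and in D2 there were 7 SS, 7 SM, 8 MS and 7 MM libraries. The total per library ran from 11518606 to 26108954 counts, with a median of 17924400. Morphine doses were not assigned to mice in the labels, so no result below refers to a dose.

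Receptor genes of the nose, which the striatum is not known to transcribe, carried counts in every library. The density over 1435 olfactory and vomeronasal receptor genes ran from 0.057 in D1 SS replicate 1 to 0.659 CPM per kb. Spread over all genes by length, this density would account for 61.4 ± 14% (SD, n = 61) of counts, from 7.46% to 86.3%. In D1 the mean share was 58.0 ± 24.3% in SS (SD, n = 8), 60.9 ± 16.3% in SM (SD, n = 8), 63.3 ± 11.4% in MS (SD, n = 9) and 53.9 ± 9.71% in MM (SD, n = 7). In D2 it was 66.9 ± 6.51% in SS (SD, n = 7), 70.2 ± 9.49% in SM (SD, n = 7), 56.9 ± 9.48% in MS (SD, n = 8) and 62.0 ± 14.9% in MM (SD, n = 7). Over the tested genes, 26.1% in D1 and 26% in D2 lay at least 2 times above this background. Of list members, 0 of 9 endothelial, 0 of 10 microglia, 1 of 10 astrocyte and 1 of 8 cortical markers did so. The same held for 1 of 20 interferon-responsive genes and for 2 of 12 oligodendrocyte and 2 of 12 interneuron markers. Changes of these lists below are therefore mostly of genes under 2 times background. The mu opioid receptor gene Oprm1 lay at 1.03 times and Fkbp5, a partner of the glucocorticoid receptor, at 1.45 times. The marker genes lay higher, with Drd2 at 14.3 times, Drd1 at 18.2 times and the enkephalin precursor Penk at 66.7 times background. Genes of the mitochondrial genome made up 0.0084% to 0.054% of counts in these sorted nuclei, and the source of these counts was not tested. Of the 13 mitochondrially encoded genes listed, 7 passed the filter on low counts, and only these were tested below. D1 SS replicate 1 also stood apart in scaling, with a TMM factor of 0.405 against a next lowest of 0.817.

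**Figure D1:**
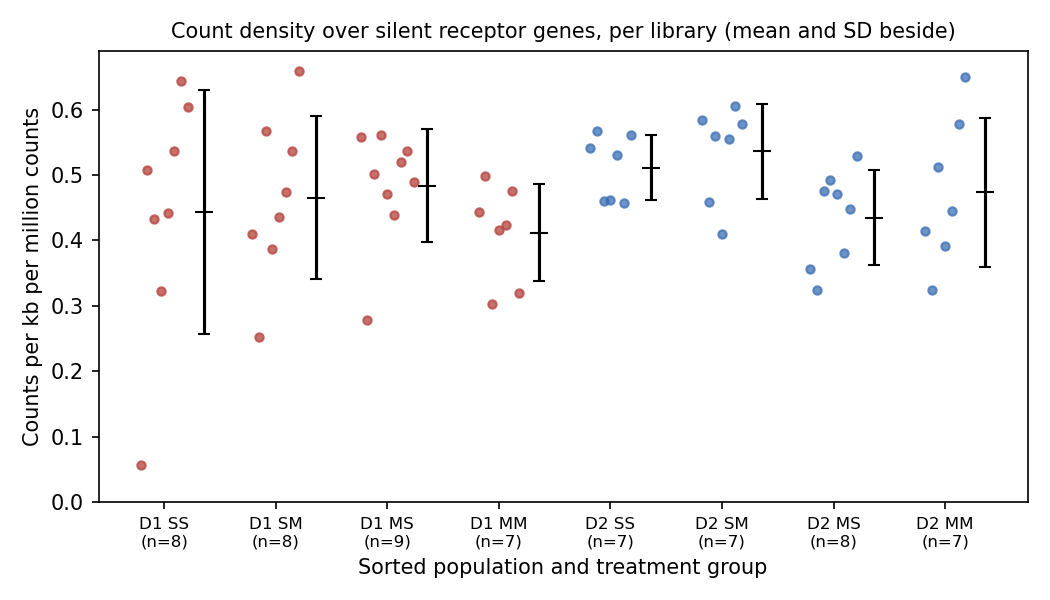
Density of counts over silent receptor genes in each library, in CPM per kb, by cell type and treatment, with group means and SD. The point at 0.057 is D1 SS replicate 1.

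The comparison of D2 with D1 nuclei in SS asks how far the sort parted the 2 cell classes. The dopamine receptor genes themselves differed most among markers. Drd2 (ENSMUSG00000032259.8, protein coding, chromosome 9, 49340627 to 49408177) was higher in D2 by a log2 of 2.61 ± 0.34 (SE, edgeR adjusted p = 8e-07), with 628 ± 201 (SD, n = 7) against 103 ± 72.5 CPM (SD, n = 8). Drd1 (ENSMUSG00000021478.6, protein coding, chromosome 13, 54051183 to 54055705) was lower, with a log2 of -3.15 ± 0.38 (SE, edgeR adjusted p = 9.4e-08), at 8.80 ± 2.24 (SD, n = 7) against 78.5 ± 78.6 CPM (SD, n = 8). Pdyn, the precursor of dynorphin, had -2.31 ± 0.29 (SE), and Tac1, the precursor of substance P, had -1.71 ± 0.31 (SE). The unscaled CPM of Drd2 lay above all 8 D1 values in 7 of 7 D2 libraries, and those of Drd1, Pdyn and Tac1 lay below all 8 in 7 of 7. Over all treatments, Drd1 stood at 63.5 ± 23.6 CPM in D1 (SD, n = 32) and 11.4 ± 3.45 in D2 (SD, n = 29), and Drd2 at 79.7 ± 23.6 in D1 (SD, n = 32) and 868 ± 392 in D2 (SD, n = 29).

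**Figure D2:**
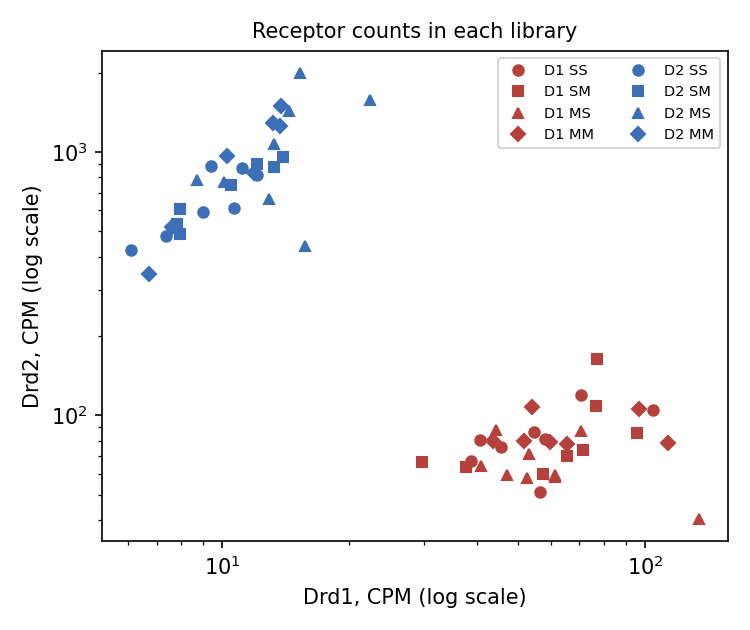
Unscaled CPM of Drd1 and of Drd2 in each library on log axes, by cell type. D1 libraries lie between 29.7 and 134 for Drd1, above all D2 libraries, which lie between 6.08 and 22.4.

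Markers of the D1 class fell as a list in D2, with 7 of 9 members lower, a median log2 of -1.84 and a camera adjusted p of 3.38e-15 (adjusted p = 5.94e-05 with an estimated correlation). The muscarinic receptor gene Chrm4 had -2.20 ± 0.44 (SE, adjusted p = 0.0133) and Slc35d3 -1.99 ± 0.31 (SE, adjusted p = 0.00013), while Isl1, a transcription factor of D1 neurons, did not pass at -0.60 ± 0.17 (SE, adjusted p = 0.0983). Markers of the D2 class rose, with 8 of 10 members higher, a median of 0.33 and an adjusted p of 3.73e-05 (adjusted p = 0.315 with an estimated correlation). Among them the adenosine receptor gene Adora2a at 0.91 ± 0.27, Penk at 1.06 ± 0.37 and the orphan receptor gene Gpr6 at 1.09 ± 0.31 (SE) did not pass in edgeR, with an adjusted p of 0.0983 each. Adjusted over the list alone, 7 D1 and 6 D2 markers passed.

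Genes beside both receptors differed along with them. In D2, Ttc12 (ENSMUSG00000040219.4, chromosome 9, 49436963 to 49486225) was higher by a log2 of 2.04 ± 0.14 (SE, edgeR adjusted p = 1.63e-17), with 130 ± 7.23 (SD, n = 7) against 31.6 ± 9.52 CPM (SD, n = 8). Its neighbour Ankk1 had 1.98 ± 0.18 (SE), and Gm4894, outside the naming rule, 1.12 ± 0.14 (SE). Sfxn1 (ENSMUSG00000021474.9, chromosome 13, 54071869 to 54108342), a mitochondrial serine transporter gene beside Drd1, was lower at -2.03 ± 0.18 (SE, adjusted p = 4.85e-12). It is also a member of the D1 marker list, the one with the smallest p. In a stretch of 253 kb around Drd1, 6 neighbours lay at 2.79 to 6.09 times background in D1 and 0.99 to 1.94 times in D2. In 236 kb around Drd2, 3 neighbours lay at 2.73 to 9.9 times in D2 and 1.43 to 2.15 times in D1. Both stretches were bounded after the values were seen. Within 400 kb, the 10 other genes near Drd1 had log2 ratios of D2 to D1 from -0.48 to 0.17 and the 8 near Drd2 from -0.22 to -0.04.

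**Figure D3:**
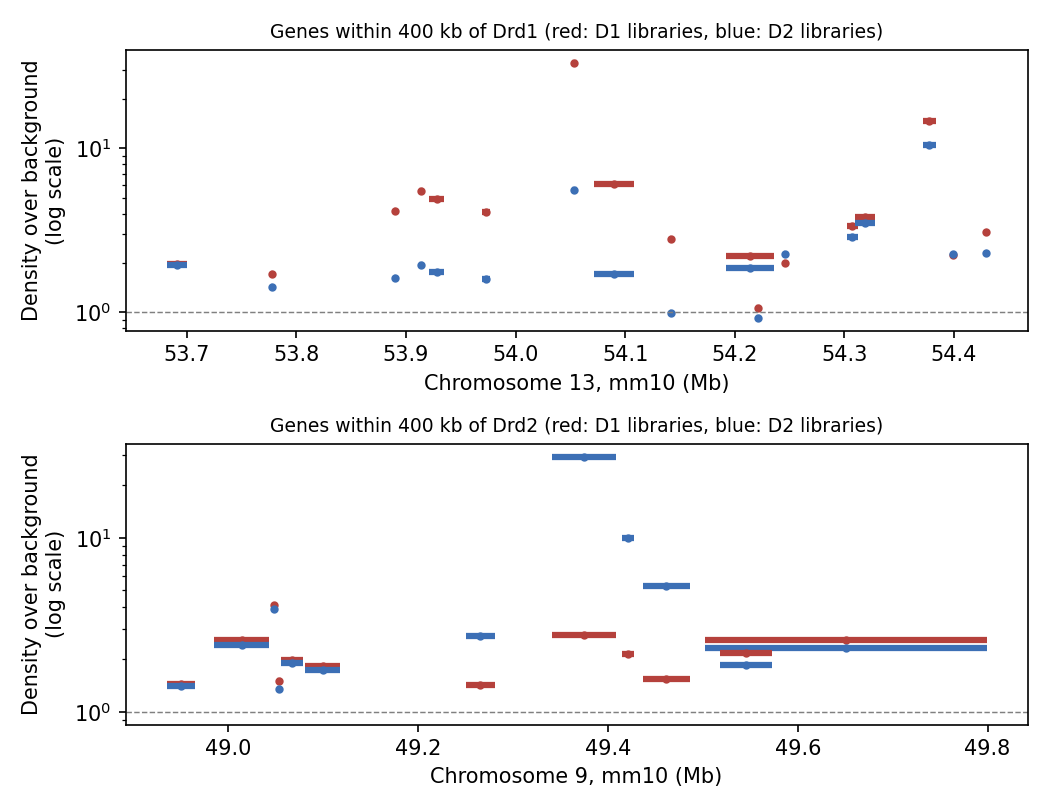
Density over background, on a log scale, of genes within 400 kb of Drd1 and of Drd2 by position, as means of 31 D1 libraries (without D1 SS replicate 1, red) and 29 D2 libraries (blue). Drd1 lies at 33.41 times background in D1 and 5.55 in D2, and Drd2 at 2.75 in D1 and 29.27 in D2.

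In all, edgeR called 20 genes between D2 and D1 in SS, 5 higher and 15 lower in D2, of which 8 fall outside the naming rule, and 11972 had an unadjusted p under 0.05 (1526 without D1 SS replicate 1). Besides the genes above, the call took in the cortical glutamate transporter gene Slc17a7 (ENSMUSG00000070570.5) at -2.44 ± 0.50, the matricellular gene Ccn2 at -2.68 ± 0.55 and the synaptic adhesion gene Lingo2 at -0.73 ± 0.15 (SE). These rest on D1 SS replicate 1, without which Slc17a7 stood at -0.48, Ccn2 at -0.44 and Lingo2 at -0.41. Chrm4 without it stood at -1.71 (adjusted p = 0.248), and 5 higher and 10 lower genes were called, 15 of them among the 20. DESeq2 called 9705 genes (541 higher, 9164 lower) and limma voom 33 (18 higher, 15 lower), while its size factors in edgeR gave 8241 (329 higher, 7912 lower) and moved log2 values by a median of -0.28 over 79 named genes.

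Most other lists were lower in D2 than in D1 SS nuclei, 15 of 24 in all. Nuclear oxidative phosphorylation genes had 36 of 36 measured identifiers lower (median -0.43, adjusted p = 1.13e-11) and cytosolic ribosomal protein genes 35 of 35 (median -0.44, adjusted p = 6.08e-10). Neither they nor the lists that follow passed otherwise, with adjusted p = 0.315 or, for the cortical markers, adjusted p = 0.332 with an estimated correlation. All 29 potassium and sodium channel genes (median -0.46, 1.08e-08), all 26 synaptic vesicle genes (-0.49, 1.55e-08), all 26 dopamine and cAMP signalling genes (-0.39, 3.04e-07), all 18 circadian clock genes (-0.45, 1.22e-05) and all 14 GABA receptor genes (-0.32, 0.000163) were lower. So were 37 of 39 chromatin regulators (-0.34, 1.55e-08), 30 of 31 synaptic adhesion genes (-0.36, 3.31e-08), 15 of 18 heat shock genes (-0.51, 6.39e-05), 7 of 7 mitochondrially encoded genes (-0.68, 6.39e-05), 27 of 31 immediate early genes (-0.31, 0.000122), 21 of 24 glutamate receptor genes (-0.33, 0.000284) and 7 of 8 cortical neuron markers (-0.21, 0.0327). Lists not called were glucocorticoid-responsive genes (median -0.18, adjusted p = 0.242), opioid receptors and peptides (0.10, 0.403), interferon-responsive genes (0.21, 0.0777) and striatal interneuron markers (0.08, 0.784). The markers of oligodendrocytes (0.18, 0.48), astrocytes (0.20, 0.118), microglia (0.28, 0.128) and endothelial cells (0.33, 0.0561) were not called either. Of list members, 9 passed over all genes and 260 adjusted over the list alone. When D1 SS replicate 1 was left out, 2 lists rose and 12 fell, with smaller medians. They were -0.10 for immediate early genes (adjusted p = 0.0455), -0.21 for oxidative phosphorylation, -0.23 for ribosomal protein, -0.16 for channel and clock, -0.19 for vesicle, -0.14 for dopamine signalling, -0.10 for chromatin regulator, -0.06 for adhesion and -0.27 for heat shock genes. The glutamate receptor (-0.06), GABA receptor (-0.10) and cortical marker (-0.01) lists were then not called. With the background as a covariate 2 rose and 6 fell. The medians then shrank to -0.03 for immediate early genes (adjusted p = 0.315), -0.10 for oxidative phosphorylation and ribosomal protein genes, -0.05 for vesicle genes, -0.03 for channel and adhesion genes, -0.02 for chromatin regulators, -0.01 for clock genes and 0 for dopamine signalling genes. The mitochondrially encoded genes kept -0.61, the D1 markers -1.34 and the D2 markers 0.40.

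Morphine challenge alone, SM against SS, asks for the acute response. In D1 nuclei no gene passed in edgeR, where the smallest adjusted p was 0.955. The genes taken by the naming rule shared it: Slc17a7 at a log2 of -2.42 ± 0.61, Ccn2 at -2.44 ± 0.66, the axon guidance gene Ntng2 at -1.32 ± 0.40, the cortical transcription factor gene Neurod2 at -1.12 ± 0.36 and the nuclear receptor gene Nr4a2 at -0.98 ± 0.32 (SE, 8 against 8 libraries). Slc17a7 stood at 10.4 ± 1.99 CPM in SM (SD, n = 8) and 56.1 ± 118 in SS (SD, n = 8). Among fixed genes, Fos, a marker of recent neuronal activity, had -0.37 ± 0.24, the synaptic plasticity gene Arc -0.86 ± 0.47, the glucocorticoid-induced genes Fkbp5 0.02 ± 0.10 and Sgk1 -0.26 ± 0.23, and Oprm1 -0.04 ± 0.09 (SE). The striatal genes Drd1 at -0.25, Drd2 at -0.19, Adora2a at -0.18, Penk at -0.11, Tac1 at -0.10 and Pdyn at 0.05 did not pass.

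By list, 12 fell and 1 rose in D1 SM against SS. Synaptic adhesion genes were lower in 30 of 31 (median -0.19, camera adjusted p = 2.69e-05), channel genes in 29 of 29 (-0.17, 3.85e-05) and immediate early genes in 28 of 31 (-0.16, 0.000298), while the 7 mitochondrially encoded genes were all higher (0.37, 0.00345). Cortical neuron markers were lower in 7 of 8 (-0.26, 0.000235). Each had adjusted p = 0.674 with an estimated correlation. Per library, the mean of the mitochondrially encoded genes differed by 0.37 (exact permutation p = 0.186), or by 0.23 without SM replicate 3 (exact permutation p = 0.366). Given the background as a covariate 2 lists rose and 2 fell, the latter with the cortical markers at -0.18 (adjusted p = 0.0018), and the medians were -0.02 for adhesion, 0.06 for channel and -0.02 for immediate early genes and 0.45 for the mitochondrially encoded genes. Of members, 0 passed over all genes and 3 adjusted over the list alone, all of the cortical markers. No gene was called by edgeR, with 770 at an unadjusted p under 0.05, or by DESeq2 or limma voom (0 each). D1 SS replicate 1 decides the falls: without it 8 lists rose and 1 fell, the medians were 0.01 for immediate early, 0.07 for adhesion, 0.12 for channel and -0.09 for cortical marker genes (the last with adjusted p = 0.134), that of the mitochondrially encoded genes was 0.51, and Slc17a7 stood at -0.47, Ccn2 at -0.18 and Ntng2 at -0.05.

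A history of morphine with a saline challenge, MS against SS, asks what remained after withdrawal. In D1 nuclei Slc17a7 had a log2 of -2.34 ± 0.58, Ccn2 -2.23 ± 0.63, Ntng2 -1.30 ± 0.39, the kainate receptor gene Grik3 -1.21 ± 0.35 and the lysosomal nuclease gene Dnase2a -0.92 ± 0.28 (SE, 9 against 8 libraries), none of which passed (edgeR adjusted p = 0.824 each). Among fixed genes Drd2 had -0.69 ± 0.27, Adora2a -0.51 ± 0.24, Arc -0.71 ± 0.45 and Fos -0.31 ± 0.24 (SE). Chromatin regulator genes were lower in 37 of 39 (median -0.18, camera adjusted p = 8.11e-07), channel genes in 29 of 29 (-0.24, 8.11e-07), synaptic adhesion genes in 31 of 31 (-0.21, 8.24e-07) D2 markers in 9 of 10 (-0.22, 0.00306) and cortical neuron markers in 7 of 8 (-0.26, 0.000141). Each had adjusted p = 0.574 with an estimated correlation, the smallest over the lists. In all, 14 lists fell and 0 rose, against 3 and 2 with the background as a covariate, where the medians were 0.04 for chromatin regulators, 0.05 for channel genes, 0.03 for adhesion genes, -0.07 for D2 markers and -0.16 for cortical markers (adjusted p = 0.000837). Of members, 0 passed over all genes and 6 adjusted over the list alone, 4 of them cortical markers. In edgeR 0 genes were called (1101 at an unadjusted p under 0.05), and DESeq2 and limma voom called 0 each. Without D1 SS replicate 1, 1 list rose and 0 fell, and 453 genes had an unadjusted p under 0.05. The medians were then 0.03 for chromatin regulators and adhesion genes, 0.04 for channel genes, -0.13 for D2 markers and -0.08 for cortical markers, and Slc17a7 stood at -0.40, Ccn2 at 0.02 and Grik3 at -0.17.

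Morphine at both times, MM against SS, gave few list calls in D1 nuclei. Ribosomal protein genes rose in 34 of 35 (median 0.21, camera adjusted p = 0.00062), immediate early genes in 22 of 31 (0.24, 0.00062) and oligodendrocyte markers in 9 of 12 (0.21, 0.0114), and synaptic adhesion genes fell in 30 of 31 (-0.05, 0.0114). The smallest was adjusted p = 0.562 with an estimated correlation. Per library, the immediate early gene mean differed by 0.24 (exact permutation p = 0.381, 0.982 adjusted over the lists). With the background regressed out it differed by 0.31 (exact permutation p = 0.0309, not adjusted over the lists). Of the adhesion genes the median edgeR log2 was -0.27, so that the edgeR fold changes behind the member counts and the log2 CPM behind the medians part here. The cause of the gap was not tested. Under the background covariate 6 lists rose and 0 fell, with medians of 0.27 for ribosomal protein, 0.29 for immediate early and 0.02 for adhesion genes. The activity-induced gene Fosb had a log2 of 0.45 ± 0.21, Arc 0.35 ± 0.47, Pdyn 0.33 ± 0.35, Tac1 0.36, Oprm1 -0.11 ± 0.09 and Sgk1 -0.24 (SE where given, 7 against 8 libraries). The naming rule took the noncoding gene AC132452.2 at 0.76 ± 0.21, the protease gene Klk7 at 0.55 ± 0.15, Rdm1 at 0.49 ± 0.16, Cabp2 at 0.45 ± 0.15 and Clec3b at 0.42 ± 0.14 (SE). None passed in edgeR (adjusted p = 1), where 790 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 each. Of list members, 0 passed over all genes and 0 adjusted over the list alone. Without D1 SS replicate 1, 16 lists rose and 0 fell, 2331 genes had an unadjusted p under 0.05, the immediate early gene median was 0.41, the ribosomal protein gene median 0.39, the adhesion gene median 0.23 and the oligodendrocyte marker median 0.11 (adjusted p = 0.106).

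Within mice with a morphine history, MM against MS asks for the response to the morphine challenge. In D1 nuclei it went with higher immediate early genes, which neurons switch on within minutes of activity. They rose in 30 of 31, with a median log2 of 0.37 and a camera adjusted p of 9.72e-17 (adjusted p = 0.194 with an estimated correlation). Npas4 (ENSMUSG00000045903.9, chromosome 19, 4984355 to 4990316), a transcription factor induced by neuronal activity, had 1.32 ± 0.39 (SE), with 37.2 ± 23.2 (SD, n = 7) against 14.9 ± 5.78 CPM (SD, n = 9). Nr4a3 (ENSMUSG00000028341.9, chromosome 4, 48045153 to 48086447) had 0.78 ± 0.21 (SE), at 71.8 ± 26.4 (SD, n = 7) against 41.9 ± 4.80 CPM (SD, n = 9). Fosl2 had 0.88 ± 0.25, Btg2 0.61 ± 0.18, Egr2 0.40 ± 0.12, Nr4a1 1.07 ± 0.39, Arc 1.06 ± 0.46 and Fos 0.65 ± 0.24 (SE). Singly none passed over all genes (edgeR adjusted p = 0.988), and 9 passed adjusted over the list alone.

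Per library, the mean over the 31 immediate early genes was 3.63 ± 0.39 log2 CPM in D1 MM (SD, n = 7) and 3.21 ± 0.22 in D1 MS (SD, n = 9), a difference of 0.42 (exact permutation p = 0.0126, two-sided, 0.2 adjusted over the 24 lists). It lay above the MS mean in 6 of 7 MM libraries. Without MM replicate 3, whose leaving out moved it furthest, the difference was 0.31 (exact permutation p = 0.0322). The background share was lower in MM (53.9%) than in MS (63.3%). Within D1 libraries, taken about their group means, the list mean went down with log2 background (Pearson r = -0.85, permutation p = 1e-05, the smallest the draws can give, rho = -0.86, r = -0.81 without the 2 farthest libraries, n = 32). With the background regressed out by a single slope over all D1 libraries, the difference was 0.30 (exact permutation p = 0.012, not adjusted over the lists).

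**Figure D4:**
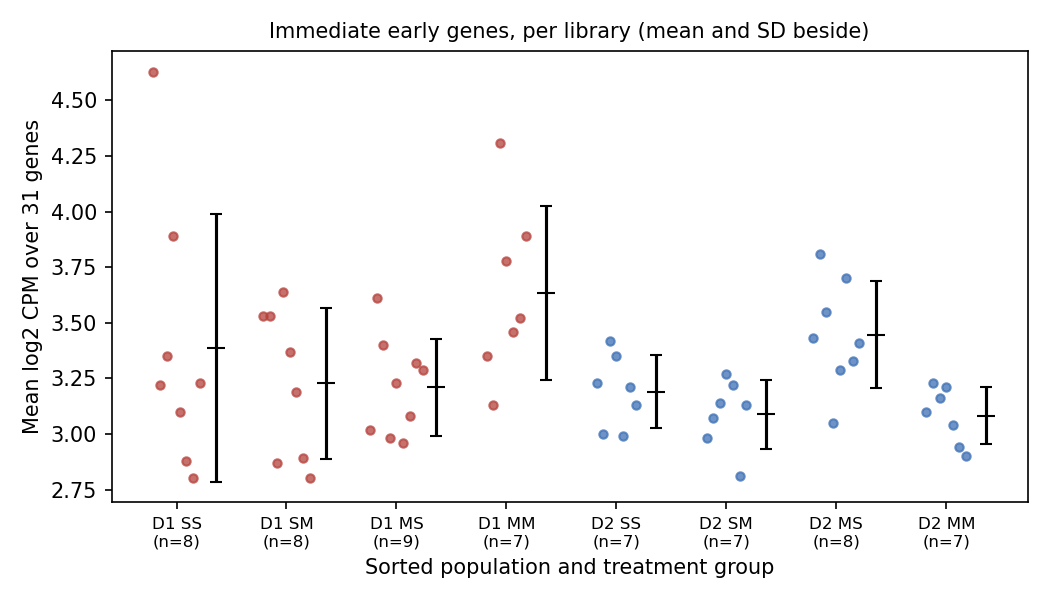
Mean log2 CPM over 31 immediate early genes in each library by cell type and treatment, with group means and SD. D1 MM stands at 3.63 against 3.21 in D1 MS, and D2 MM at 3.08 against 3.45 in D2 MS.

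Other lists rose with them in D1 MM against MS, 18 of 24 in all with 0 lower. Ribosomal protein genes rose in 34 of 35 (median 0.32, adjusted p = 2.51e-11), oxidative phosphorylation genes in 36 of 36 (0.22, 1.83e-06), synaptic vesicle genes in 25 of 26 (0.30, 9.67e-06), D2 markers in 8 of 10 (0.42, 6.07e-05) and mitochondrially encoded genes in 7 of 7 (0.43, 6.07e-05; library means, exact permutation p = 0.213). None passed otherwise, from adjusted p = 0.194 for D2 markers to adjusted p = 0.473 with an estimated correlation. Markers of other cells rose too, those of cortical neurons in 6 of 8 (0.19, 0.0424) and of oligodendrocytes in 10 of 12 (0.09, 0.0483), both with adjusted p = 0.473 with an estimated correlation. Striatal interneuron markers rose in 8 of 12 (0.07, 0.0222; adjusted p = 0.194 with an estimated correlation). Of genes with an unadjusted p under 0.05 that were higher in MM, 67.5% lay at least 2 times above background. By gene, edgeR called 0, DESeq2 0 and limma voom 1. At an unadjusted p under 0.05 stood 940 genes, or 2019 without D1 SS replicate 1, where chance alone would give about 2054. With the background as a covariate 6 lists rose and 0 fell, with a median of 0.26 and an adjusted p of 1.69e-11 for the immediate early genes. The medians were then 0.15 for ribosomal protein, 0.25 for D2 marker, 0.37 for mitochondrially encoded, 0.13 for oligodendrocyte marker and 0.11 for interneuron marker genes, and 0.05 for oxidative phosphorylation, 0.09 for vesicle and 0.09 for cortical marker genes, which were no longer called.

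Both groups of MM against SM received morphine last and differ in history. In D1 nuclei the immediate early genes rose again, in 29 of 31, with a median log2 of 0.37 and a camera adjusted p of 4.13e-17 (adjusted p = 0.261 with an estimated correlation). Npas4 had 1.27 ± 0.41, Egr2 0.39 ± 0.13 and Fos 0.72 ± 0.25 (SE, 7 against 8 libraries), and the antisense gene Fhad1os2 0.34 ± 0.11 and Coa4, an assembly factor of cytochrome oxidase, -0.36 ± 0.12 (SE), none passing in edgeR (adjusted p = 1). Heat shock genes rose in 18 of 18 (0.34, adjusted p = 3.08e-06; adjusted p = 0.37 with an estimated correlation). Oligodendrocyte markers rose in 9 of 12 (0.12, 0.00894; adjusted p = 0.292 with an estimated correlation). Their mean per library was 3.22 ± 0.13 log2 CPM in MM (SD, n = 7) and 3.08 ± 0.04 in SM (SD, n = 8), with an exact permutation p of 0.000932 (0.0224 adjusted over the lists, 0.0523 with the background regressed out). The myelin gene Mog at 0.25 ± 0.11 (SE) did not pass singly.

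In that comparison the immediate early gene mean per library differed by 0.41 (exact permutation p = 0.0483, 0.444 adjusted over the lists) and lay above the SM mean in 6 of 7 MM libraries. Without MM replicate 3 the difference was 0.29 (exact permutation p = 0.111). In all, 13 lists rose and 0 fell, with 0 members passing over all genes and 0 adjusted over the list alone. Called genes numbered 0 in edgeR (550 at an unadjusted p under 0.05, and 1181 without D1 SS replicate 1), and DESeq2 and limma voom called 0 each. With the background as a covariate 6 lists rose and 0 fell, with medians of 0.31 for immediate early, 0.23 for heat shock and 0.10 for oligodendrocyte marker genes.

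The interaction asks whether the response to the challenge differed with history. In D1 nuclei it was largest in list terms for immediate early genes, higher in 28 of 31 with a median log2 of 0.61 (camera adjusted p = 5.4e-13; adjusted p = 0.407 with an estimated correlation). Cortical neuron markers were higher in 7 of 8 (0.44, 0.000336; adjusted p = 0.407 with an estimated correlation). Npas4 had 1.82 ± 0.56 (SE), with 37.2 ± 23.2 in MM (SD, n = 7), 14.9 ± 5.78 in MS (SD, n = 9), 15.4 ± 6.41 in SM (SD, n = 8) and 21.8 ± 19.5 CPM in SS (SD, n = 8). Slc17a7 had 3.71 ± 0.84, Ccn2 3.45 ± 0.93, Neurod2 1.70 ± 0.51 and the noncoding gene AC122818.4 -0.69 ± 0.21 (SE), and none of these passed (edgeR adjusted p = 0.782). In all, 14 lists rose and 0 fell, with the smallest adjusted p = 0.407 with an estimated correlation, and 0 members passed over all genes and 13 adjusted over the list alone. No gene was called by edgeR (952 at an unadjusted p under 0.05) or DESeq2 (0), and limma voom called 1. Without D1 SS replicate 1, 12 lists rose and 0 fell, 630 genes had an unadjusted p under 0.05, the cortical marker median was 0.18 with the list still called, and Slc17a7 stood at 1.77 and Ccn2 at 1.19. With the background as a covariate 5 lists rose and 0 fell, and the medians were 0.34 for immediate early genes (adjusted p = 7.26e-12) and 0.26 for cortical markers (adjusted p = 0.00208).

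In D2 nuclei of SM against SS the mitochondrially encoded genes, which code for respiratory chain subunits, rose in 7 of 7 with a median log2 of 0.64 (camera adjusted p = 3.96e-08; adjusted p = 0.49 with an estimated correlation). The complex I gene mt-Nd1 had 1.12 ± 0.38 (SE), at 6.92 ± 5.94 (SD, n = 7) against 3.15 ± 0.416 CPM (SD, n = 7). D2 SM replicate 1 carries much of this: the difference of the list mean per library was 0.66 with it (exact permutation p = 0.0227, 0.272 adjusted over the lists) and 0.38 without it (exact permutation p = 0.0478, 6 against 7 libraries). The list test was not repeated without it. Ribosomal protein genes rose in 32 of 35 (0.14, 4.86e-06) and oxidative phosphorylation genes in 30 of 36 (0.10, 0.00106), each with adjusted p = 0.989 with an estimated correlation. Microglia markers fell in 8 of 10 (-0.12, 0.0277), interferon-responsive genes in 16 of 20 (-0.07, 0.0277) and immediate early genes in 25 of 31 (-0.09, 0.0334). Their adjusted p was 0.525, 0.833 and 0.989 with an estimated correlation. At least 2 times above background lay 0 of 10 microglia markers and 1 of 20 interferon-responsive genes. The immediate early genes were not called with the background as a covariate (-0.05, adjusted p = 0.133). Their mean per library differed by -0.10 (exact permutation p = 0.253), or -0.06 without SM replicate 6. Fos had -0.17 ± 0.15, Arc -0.46 ± 0.31, Sgk1 -0.14, Oprm1 0.01, Fkbp5 -0.01, Drd2 0.14 and Penk 0.07 (SE where given).

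Under the naming rule, D2 SM against SS gave Lonrf3 at 0.29 ± 0.07, Smim11 at -0.30 ± 0.07, the pseudogene AC122861.2 at -0.55 ± 0.15, Exoc3l at -0.33 ± 0.09 and the zinc finger gene Zscan12 at 0.27 ± 0.08 (SE, 7 against 7 libraries), none of which passed in edgeR (adjusted p = 1, against a smallest of 0.39 over all genes). In all, 3 lists rose and 3 fell, against 8 and 3 with the background as a covariate, where endothelial markers (-0.09) took the place of the immediate early genes, with 0 members passing over all genes and 7 adjusted over the list alone. By gene, edgeR called 0 (1333 at an unadjusted p under 0.05), and DESeq2 and limma voom called 0 each.

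In D2 nuclei of MS against SS, mitochondrially encoded genes rose in 7 of 7, with a median log2 of 1.09 (camera adjusted p = 7.33e-07; adjusted p = 0.211 with an estimated correlation), among them the cytochrome oxidase gene mt-Co1 (ENSMUSG00000064351.1) at 17.0 ± 5.92 (SD, n = 8) against 7.19 ± 1.55 CPM (SD, n = 7). Nuclear oxidative phosphorylation genes rose in 36 of 36 (0.38, 1.12e-14), ribosomal protein genes in 35 of 35 (0.41, 2.99e-12), synaptic vesicle genes in 25 of 26 (0.56, 1.56e-09) and dopamine and cAMP signalling genes in 24 of 26 (0.51, 4.07e-09), again each with adjusted p = 0.211 with an estimated correlation. Markers of D2 neurons rose in 9 of 10 (0.58, 0.000329) and immediate early genes in 24 of 31 (0.20, 0.000288), while endothelial markers fell in 9 of 9 (-0.24, 0.00286). Of the endothelial markers, 0 of 9 lay at least 2 times above background. Among fixed genes, Adora2a had 0.87 ± 0.28, Penk 0.75 ± 0.27, Drd2 0.91 ± 0.36, Drd1 0.75 ± 0.24, Tac1 0.61 ± 0.19, Arc 0.71 ± 0.29, Oprm1 0.01 and Fkbp5 -0.01 ± 0.07 (SE where given, 8 against 7 libraries). In all, 14 lists rose and 3 fell, none under adjusted p = 0.211 with an estimated correlation. Under the background covariate 13 rose and 3 fell. The medians were then 0.99 for mitochondrially encoded, 0.21 for oxidative phosphorylation, 0.20 for ribosomal protein, 0.12 for immediate early and -0.12 for endothelial genes, and 0.18 each for vesicle, dopamine signalling and D2 marker genes.

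No single gene of D2 MS against SS passed in edgeR, where the smallest adjusted p was 0.0713. It was shared by Dtymk, which makes thymidine diphosphate, at 0.48 ± 0.09, the sterol transporter gene Abcg8 at -0.33 ± 0.07, Mmgt1 at 0.58 ± 0.12, the egg coat gene Zp1 at -0.48 ± 0.10 and Fam206a at 0.50 ± 0.10 (SE). At an unadjusted p under 0.05 stood 13164 genes (7646 higher, 5518 lower), the most within a cell type. DESeq2 called 6641 (5146 higher, 1495 lower) and limma voom 3485 (1879 higher, 1606 lower). Of list members, 0 passed over all genes and 255 adjusted over the list alone. The background share was 56.9% in MS and 66.9% in SS, a log2 density difference of -0.25 (exact permutation p = 0.0434, two-sided, 0.434 adjusted over 10 comparisons). Of the nominally higher genes 61.1% lay at least 2 times above background, against 10.7% of the lower.

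Per library, the mean over the mitochondrially encoded genes was 3.18 ± 0.58 log2 CPM in D2 MS (SD, n = 8) and 2.12 ± 0.30 in D2 SS (SD, n = 7), above the SS mean in 8 of 8 libraries (difference 1.07, exact permutation p = 0.00249, 0.0234 adjusted over the lists). With the background regressed out it was 1.00 (exact permutation p = 0.00264). As D2 minus D1, the difference in MS against SS was 1.19 (permutation p = 0.0056, 0.028 adjusted over 5 contrasts). This test, chosen after the results were seen, was run only for the mitochondrially encoded and the immediate early genes and was not adjusted over lists.

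In D2 nuclei of MM against SS, synaptic adhesion genes rose in 28 of 31 (median log2 0.25, camera adjusted p = 3.44e-09; adjusted p = 0.349 with an estimated correlation), among them Lrfn5 at 0.37 ± 0.12 (SE). Oxidative phosphorylation genes rose in 36 of 36 (0.19, 5.77e-08), dopamine and cAMP signalling genes in 25 of 26 (0.29, 8.97e-07) and glutamate receptor genes in 17 of 24 (0.26, 7.35e-05), the last with the metabotropic receptor gene Grm5 at 0.61 ± 0.21 (SE). Interferon-responsive genes fell in 16 of 20 (-0.15, 0.0056) and astrocyte markers in 9 of 10 (-0.10, 0.0327). Only 1 of 20 and 1 of 10 of them lay at least 2 times above background. In all, 12 lists rose and 3 fell, each with adjusted p = 0.349 with an estimated correlation. Given the background as a covariate 11 rose and 2 fell, with medians of 0.14 for adhesion, 0.07 for oxidative phosphorylation, 0.12 for dopamine signalling and 0.13 for glutamate receptor genes. The falls were then of interferon-responsive (-0.14) and immediate early genes (-0.18, adjusted p = 0.000436), and astrocyte markers (-0.12, adjusted p = 0.163) were not called. Drd2 had 0.66 ± 0.36, Penk 0.27 ± 0.27, Arc -0.59 ± 0.31, Fos -0.22 ± 0.15, Fkbp5 0.08 ± 0.07 and Oprm1 0.02 ± 0.05 (SE, 7 against 7 libraries).

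Of genes taken by the naming rule, D2 MM against SS had the cytokine gene Il20 at -0.51 ± 0.11, D3Ertd751e at 0.30 ± 0.07, the ubiquitin ligase gene Trim7 at -0.29 ± 0.07, Zim2 at -0.36 ± 0.09 and Dtx3l at -0.31 ± 0.08 (SE), none passing (edgeR adjusted p = 0.361). No gene was called by edgeR, with 5472 at an unadjusted p under 0.05, or by DESeq2 or limma voom (0 each). Of list members, 0 passed over all genes and 9 adjusted over the list alone.

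The challenge within D2 mice of a morphine history, MM against MS, went with lower immediate early genes. They fell in 26 of 31, with a median log2 of -0.28 and a camera adjusted p of 2.98e-17 (adjusted p = 0.0258 with an estimated correlation). Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984), a transcription factor gene induced by synaptic activity, had -1.23 ± 0.25 (SE), at 17.2 ± 4.60 (SD, n = 7) against 40.5 ± 20.6 CPM (SD, n = 8). Arc (ENSMUSG00000022602.14, chromosome 15, 74669083 to 74672570) had -1.30 ± 0.30 (SE), at 7.72 ± 1.84 (SD, n = 7) against 19.1 ± 9.23 CPM (SD, n = 8). Nr4a1 had -0.88 ± 0.21, Junb -0.88 ± 0.23, the kinase phosphatase gene Dusp6 -0.64 ± 0.16 and Fos -0.35 ± 0.14 (SE). Outside the list, the transcription factor genes Klf5 at -0.54 ± 0.11 and Etv5 at -0.40 ± 0.09, the small GTPase gene Arl4d at -0.74 ± 0.18 and the mitochondrial ribosome gene Mrpl18 at -0.44 ± 0.10 (SE) had the smallest p. Singly none passed over all genes (edgeR adjusted p = 0.973), and 16 of the immediate early genes passed adjusted over the list alone.

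Per library, the immediate early gene mean was 3.08 ± 0.13 log2 CPM in D2 MM (SD, n = 7) and 3.45 ± 0.24 in D2 MS (SD, n = 8), below the MS mean in 7 of 7 MM libraries. The difference was -0.36 (exact permutation p = 0.00373, two-sided, 0.0895 adjusted over the lists), and with the background regressed out -0.31 (exact permutation p = 0.00155, 0.0372 adjusted). Against SS the mean differed by 0.26 in MS (0.31 without MS replicate 4, exact permutation p = 0.00758) and by -0.11 in MM. Against SM it differed by -0.01 in MM. Most of the gap between MM and MS thus lies in the higher values of MS. Within D2 libraries the list mean went down with log2 background (Pearson r = -0.67, permutation p = 8e-05, rho = -0.64, r = -0.60 without the 2 farthest, n = 29). As D2 minus D1, the difference in MM against MS was -0.79 (permutation p = 0.00011, 0.00055 adjusted over 5 contrasts). Like that of the mitochondrially encoded genes, the only other list tested so, it was not adjusted over lists. The test was chosen after the results were seen, and MM against MS was not among the planned comparisons between cell types. Its p values are therefore not those of a planned test.

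Other lists fell alongside in D2 MM against MS, 11 of 24 in all with 1 higher. Oxidative phosphorylation genes fell in 36 of 36 (median -0.21, 9.45e-10) and ribosomal protein genes in 35 of 35 (-0.18, 1.97e-09). Each had adjusted p = 0.567 with an estimated correlation. Heat shock genes fell in 16 of 18 (-0.30, 5.2e-07), with Hspa8 at -0.59 ± 0.23 (SE), and mitochondrially encoded genes in 7 of 7 (-0.63, 5.26e-06; library means, exact permutation p = 0.0549), both with adjusted p = 0.451 with an estimated correlation. Endothelial markers rose in 8 of 9 (0.07, 0.0293, and adjusted p = 0.567 with an estimated correlation), with 0 of 9 at least 2 times above background. By gene, edgeR called 0 (1548 at an unadjusted p under 0.05, against about 2056 by chance), limma voom 0 and DESeq2 1. Of list members, 0 passed over all genes and 20 adjusted over the list alone. With the background as a covariate 1 list rose and 6 fell, with an adjusted p of 9.77e-15 and a median of -0.24 for the immediate early genes. Oxidative phosphorylation and ribosomal protein genes then had -0.11 each, heat shock genes -0.20 and mitochondrially encoded genes -0.59. The list that rose was synaptic adhesion genes (0.05, adjusted p = 0.00179), while endothelial markers (0.04, adjusted p = 0.171) were no longer called.

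History under a morphine challenge, MM against SM, was led in D2 nuclei by synaptic adhesion genes. They rose in 28 of 31 (median log2 0.22, camera adjusted p = 5.88e-11; adjusted p = 0.434 with an estimated correlation), with Cntnap2 at 0.30 ± 0.08 (SE), and channel genes in 26 of 29 (0.23, 1.41e-06; adjusted p = 0.473 with an estimated correlation), with the potassium channel genes Kcnip4 at 0.67 ± 0.18 and Kcnd2 at 0.75 ± 0.24 (SE, 7 against 7 libraries). GABA receptor genes rose in 13 of 14 (0.25, 4.76e-06) and glutamate receptor genes in 18 of 24 (0.29, 1.38e-05), with Grm5 at 0.65 ± 0.21 (SE), each list with adjusted p = 0.434 with an estimated correlation. Astrocyte markers fell in 10 of 10 (-0.11, 0.0423) and cortical neuron markers in 7 of 8 (-0.12, 0.0316), both with adjusted p = 0.473 with an estimated correlation. Only 1 of 10 astrocyte and 1 of 8 cortical markers lay at least 2 times above background. In all, 10 lists rose and 2 fell. Without a background covariate the immediate early genes did not pass, with a mean of 3.08 ± 0.13 in MM (SD, n = 7) and 3.09 ± 0.15 in SM (SD, n = 7).

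The background share in D2 MM (62.0%) was lower than in SM (70.2%), and with it as a covariate 3 lists rose and 4 fell. The medians were then 0.10 for adhesion, 0.09 for GABA receptor and 0.07 for glutamate receptor genes, which stayed called, and -0.01 for channel, 0 for vesicle and -0.02 each for astrocyte and cortical marker genes, which did not. Those that fell were immediate early (-0.12, adjusted p = 0.0102), heat shock (-0.13), oxidative phosphorylation (-0.04) and ribosomal protein genes (-0.13). The naming rule took the nicotinic receptor gene Chrna6 at -0.36 ± 0.09, the helicase gene Ddx20 at 0.34 ± 0.08, Nme5 at 0.25 ± 0.06, Nutm2 at -0.38 ± 0.10 and Mctp1 at 0.38 ± 0.10 (SE), none passing (edgeR adjusted p = 0.608). No gene of this comparison was called by edgeR (3180 at an unadjusted p under 0.05), DESeq2 or limma voom (0 each), and 0 list members passed over all genes and 16 adjusted over the list alone.

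The interaction of challenge and history in D2 nuclei was led by genes of respiration and translation. Ribosomal protein genes were lower in 35 of 35 (median log2 -0.34, camera adjusted p = 2.15e-13; adjusted p = 0.476 with an estimated correlation). Mitochondrially encoded genes were lower in 7 of 7 (-1.27, 7.4e-12; adjusted p = 0.161 with an estimated correlation), and mt-Nd1 had -1.80 ± 0.51 (SE), with 4.85 ± 1.80 in MM (SD, n = 7), 7.67 ± 3.39 in MS (SD, n = 8), 6.92 ± 5.94 in SM (SD, n = 7) and 3.15 ± 0.416 CPM in SS (SD, n = 7). The SM value includes replicate 1, whose list mean of 4.47 log2 CPM stood far above the 2.50 ± 0.32 of the others (SD, n = 6), and the interaction was not repeated without it. Immediate early genes were lower in 26 of 31 (-0.24, 1.25e-05; adjusted p = 0.476 with an estimated correlation). In all, 2 lists rose and 10 fell, as many as with the background as a covariate, with 0 members passing over all genes and 9 adjusted over the list alone. Dtymk had -0.51 ± 0.13, Syt15 0.59 ± 0.15, Tmem177 -0.47 ± 0.12, Zscan12 -0.38 ± 0.11 and the proteasome assembly gene Pomp -0.34 ± 0.10 (SE), none passing (edgeR adjusted p = 0.991). In edgeR 0 genes were called (1464 at an unadjusted p under 0.05), and DESeq2 and limma voom called 0 each.

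The difference of the responses between cell types addresses what is shared and what diverges. For SM against SS, D2 minus D1, oxidative phosphorylation genes were higher in 36 of 36 (median log2 0.23, camera adjusted p = 1.07e-05), chromatin regulators in 38 of 39 (0.15, 0.000366) and cortical neuron markers in 8 of 8 (0.27, 0.00113), and microglia markers were lower in 8 of 10 (-0.24, 0.0262), each with adjusted p = 0.672 with an estimated correlation. In all 13 lists rose and 1 fell, against 3 and 0 with the background as a covariate, where the medians were 0.09, 0.02, 0.23 (adjusted p = 0.0151) and -0.19. Slc17a7 had 2.52 ± 0.68, Ccn2 2.71 ± 0.80, Il20 -0.78 ± 0.20, Olfr112 0.92 ± 0.28 and Klk7 -0.63 ± 0.19 (SE), none passing (edgeR adjusted p = 0.885). No gene was called by edgeR (1053 at an unadjusted p under 0.05), DESeq2 or limma voom (0 each), and 0 list members passed over all genes and 2 adjusted over the list alone. When D1 SS replicate 1 was left out, 0 lists were called, the medians of these 4 were 0.01, -0.06, 0.09 and -0.09, Slc17a7 stood at 0.56 and Ccn2 at 0.47.

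For MS against SS, D2 minus D1, channel genes were higher in 29 of 29 (median log2 0.64, camera adjusted p = 5.18e-09), circadian clock genes in 17 of 18 (0.83, 1.13e-07), with Per2 at 1.25 ± 0.37 (SE), and mitochondrially encoded genes in 7 of 7 (1.26e-06), with mt-Co1 at 1.51 ± 0.42 (SE) and a difference of library means of 1.19. Each had adjusted p = 0.317 with an estimated correlation, the smallest over the lists, of which 14 rose and 1 fell. Grik3 had 1.83 ± 0.44, the neurotrophin receptor gene Ntrk2 1.85 ± 0.48, Tmem177 0.59 ± 0.13, Ssbp1, which binds mitochondrial DNA, 0.71 ± 0.19 and AC122818.4 -0.78 ± 0.19 (SE), none passing (edgeR adjusted p = 0.149). Called genes numbered 0 in edgeR (10571 at an unadjusted p under 0.05), while DESeq2 called 5703 (5170 higher, 533 lower) and limma voom 7. Of list members, 0 passed over all genes and 215 adjusted over the list alone. Without D1 SS replicate 1, Grik3 stood at 0.76 and Ntrk2 at 0.82, 14 lists rose and 2 fell, with medians of 0.38 for channel and 0.51 for clock genes, and 2556 genes had an unadjusted p under 0.05. With the background as a covariate 8 lists rose and 1 fell, and the medians were 0.13 for channel, 0.20 for clock and 1.05 for mitochondrially encoded genes.

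For MM against SS, D2 minus D1, synaptic adhesion genes were higher in 30 of 31 (median log2 0.27, camera adjusted p = 4.64e-07; adjusted p = 0.557 with an estimated correlation), with Lrrtm4 at 0.92 ± 0.36 (SE). Immediate early genes were lower in 21 of 31 (-0.41, 0.000827), with Atf3 at -0.40 ± 0.14 (SE), and oligodendrocyte markers in 10 of 12 (-0.27, 0.0129), with the myelin gene Mobp at -0.48 ± 0.18 (SE). These 2 lists had adjusted p = 0.612 and adjusted p = 0.557 with an estimated correlation. Markers of microglia (-0.33, 0.0297), astrocytes (-0.28, 0.0308) and endothelial cells (-0.19, 0.0335) fell too, with adjusted p = 0.557 or, for the last, adjusted p = 0.612 with an estimated correlation. Of them 0 of 10, 1 of 10 and 0 of 9 lay at least 2 times above background. In all 9 lists rose and 6 fell, against 3 and 4 with the background as a covariate. The medians were then 0.14 for adhesion, -0.49 for immediate early and -0.22 for oligodendrocyte marker genes, and -0.25, -0.19 and -0.08 for the other markers, which were no longer called. Il20 had -0.95 ± 0.21 (edgeR adjusted p = 0.335), Clec3b -0.81 ± 0.18 (0.374), and Rdm1 -0.76 ± 0.19, the bone transcription factor gene Sp7 -0.58 ± 0.15 and Lelp1 -0.68 ± 0.18 (SE, 0.66 each), none passing. No gene was called by edgeR (2891 at an unadjusted p under 0.05), while DESeq2 called 1 and limma voom 3. Of list members, 0 passed over all genes and 0 adjusted over the list alone. Without D1 SS replicate 1, 0 lists rose and 6 fell. The medians were then -0.49 for immediate early and 0.07 for adhesion genes, and -0.15 for oligodendrocyte, -0.16 for microglia, -0.14 for astrocyte and 0.03 for endothelial markers, with adhesion, astrocyte and endothelial genes not called.

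Over the 16 comparisons, the list calls that held with an estimated correlation were the D1 markers in D2 against D1 and the immediate early genes in D2 MM against MS. The relations of the immediate early gene mean formed a family of 4, with adjusted p values of 4e-05 for background in D1 and 0.00016 in D2. The other members were the cortical marker mean in D1 (Pearson r = 0.44, permutation p = 0.11, rho = 0, r = 0.06 without the 2 farthest, adjusted 0.11, n = 32) and in D2 (r = -0.47, permutation p = 0.015, rho = -0.47, r = -0.51 without the 2 farthest, adjusted 0.02, n = 29).

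Across 40552 genes, which are not independent replicates, the fold changes against SS in D1 and D2 correlated with r = -0.09 for SM, -0.68 for MS and -0.31 for MM. Only D2 libraries were regrouped, giving values as large in 79, 1 and 0 of 100 draws. Neither leaving out D1 SS replicate 1 nor a background covariate was tried here, so opposite responses are not shown. Among 6803 genes of at least 5 log2 CPM the values were -0.16, -0.86 and -0.61, matched or passed in 92, 19 and 14 of 100 draws. Comparisons within a cell type share their SS libraries. In D1, SM and MS changes correlated with r = 0.84, SM and MM with 0.60 and MS and MM with 0.54, where simulated groups without any change gave 0.54, 0.52 and 0.53. Regrouping the D1 libraries gave medians of 0.65, 0.59 and 0.67 and values as large in 19, 47 and 59 of 100 draws. With the SS libraries split between the comparisons, the medians in D1 were -0.24, -0.44 and -0.45. In D2 the values were 0.43, 0.50 and 0.81, simulated 0.51, 0.50 and 0.52, and split 0.24, 0.20 and 0.53. Regrouping the D2 libraries gave medians of 0.53, 0.52 and 0.51 and values as large in 66, 55 and 1 of 100 draws. The covariance for MS and MM in D2 was 0.0531 against a simulated 0.0157.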

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

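All tests in this part were chosen after the results they bear on were seen. In each group of 7 to 9 libraries, the gap between the highest or lowest library and its nearest neighbour was compared with the range of the group, in 80 tests. Chance flags about 1 in 20 groups, so 4 were expected, and 6 stood out. D1 MS replicate 2 had a background density of 0.278 CPM per kb (next 0.439, group 0.484 ± 0.0868, SD, n = 9) and 134 unscaled CPM of Drd1 (next 70.7). Drd2 stood at 164 CPM in D1 SM replicate 2 (next 108, group 86.4 ± 34.8, SD, n = 8) and Arc at 17.4 CPM in D2 SM replicate 5 (next 9.34, group 8.71 ± 4.17, SD, n = 7). The cortical marker Slc17a7 stood at 140 CPM in D1 SS replicate 1 (next 31.3, group 31.2 ± 44.9, SD, n = 8). The mean of the mitochondrially encoded genes stood at 4.47 log2 CPM in D2 SM replicate 1 (next 2.81, group 2.78 ± 0.80, SD, n = 7). The responses of the cell types differed for the mitochondrially encoded genes in MS against SS (D2 minus D1 of 1.19, permutation p = 0.0056) and for the immediate early genes in MM against MS (-0.79, permutation p = 0.00011). Only these lists were tested for such differences per library.

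Silent receptor genes carried counts in every library. Transcription of these genes is argued against, since, pooled over the libraries, 96% of those of at least 5 kb lay within 2 times their median density. The ratio of X to autosomes was taken over a wider set of families treated as silent. It held 116 genes on X and 2272 on autosomes. On X the density was 0.47 of that on autosomes (median of 61 libraries, 0.44 to 0.54), where a male genome would give 0.5. The ratio is near that of genomic DNA as a source of the background. The families on X and on autosomes differ in part, which was not allowed for, so the ratio does not settle the source. It leaves open how the share came to differ between libraries, and no biological explanation was tested.

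Genes beside Drd1 and Drd2 differed between cell types along with the receptors. Extra genomic copies of these regions in the driver lines and transcription of the neighbours in the sorted cells are candidate explanations. Within D2 groups, the genes beside Drd2 had r = -0.07 with log2 background (permutation p = 0.77, rho = -0.03, n = 29), so these cannot be told apart there, while Drd2 itself had r = -0.85. Within D1 groups, the genes beside Drd1 had r = -0.54 (permutation p = 0.0037) against -0.83 for Drd1, in a family of 4.

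Immediate early genes were higher in D1 and lower in D2 in MM against MS. Background as the whole cause is argued against, since with it regressed out the D2 minus D1 difference was -0.61 (permutation p = 5e-05). The regression used a single slope for each cell type, fitted with D1 SS replicate 1 included. It was not repeated without that library, so the value holds for that slope only. Cortical neurons in the D1 MM libraries cannot be told apart from a response in D1, since adding their markers to the background moved the D1 difference only from 0.30 to 0.31. A response to the challenge that differs by cell type stays among the open explanations. Handling at the challenge and the time of day were not tested.

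Other splits of the same libraries were counted. For counts of genes, 22 of 22 splits gave as many as the real 0 in each of the 6 D1, 6 D2 and 3 difference comparisons, as any split must, so they say nothing about chance. The highest other count was 4412 in D1 MS against SS, 3923 in D2 MS against SS, 2 in D2 MM against MS and 0 in the rest. For D2 against D1 in SS, 2 of 22 splits gave as many as the real 20, with a highest other of 10557, so chance is not excluded for that count. It is a statement on the count and not on the receptors, since Drd2 lay above all 8 D1 values in 7 of 7 D2 libraries and Drd1 below them. Splits that call so many more genes than the real one point to a structure of the samples other than their groups. Which comparisons held such a split differed between this draw and an earlier one, so the counts are no property of the comparisons named.

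For counts of lists, 80 splits were drawn per comparison. Only D1 MM against MS had a share under 0.05. There 1 of 80, the real split, reached its 18 lists (highest other 16), the smallest share 80 splits can give. It was not adjusted over the 16 comparisons, so chance is not excluded. In D1, 48 splits gave as many as the real 13 for SM against SS (highest other 17), 43 as many as 14 for MS against SS (18), 78 as many as 4 for MM against SS (17), 29 as many as 13 for MM against SM (17) and 31 as many as 14 for the interaction (17). In D2, 37 gave as many as the real 6 for SM against SS (15), 4 as many as 17 for MS against SS (19), 7 as many as 15 for MM against SS (16), 30 as many as 12 for MM against MS (16), 25 as many as 12 for MM against SM (15) and 27 as many as 12 for the interaction (19). For D2 against D1 in SS, 16 gave as many as the real 16 (19), and for the differences between cell types 32 as many as 14 in SM (16), 22 as many as 15 in MS (16) and 18 as many as 15 in MM (17). The split of D1 MM against SS with 17 lists against a real 4 points to a structure of the samples. These splits were a second and smaller draw, made to shorten the computation after a first draw had been seen. In the first draw another split also reached the real count of D1 MM against MS, with its share still under 0.05. The share for D2 MS against SS fell on the other side of that threshold, so for both comparisons the outcome is a close one.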

How the results depend on the processing

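The covariate for background, that covariate with a filter at 2 times background, and leaving out D1 SS replicate 1 were chosen after the results were seen, and the other alternatives before. Where no reason is given below, the cause was not tested. The count of called genes stayed within 1.5 times its value in 16 of 16 comparisons without a filter, 15 with DESeq2 size factors, 15 with the background covariate, 15 with that and its filter, 14 with surrogate variables, 11 with DESeq2 and 10 with limma voom, and in 10 of 10 without D1 SS replicate 1. Of 996 named results, 819 kept their direction and side of the threshold with DESeq2 (177 passed newly), 938 with its size factors, 996 without a filter, 933 with limma voom and 991 with surrogate variables. With the background covariate 1091 of 1206 did (78 no longer passed, 35 reversed), with its filter 595 of 599, and without D1 SS replicate 1 it was 714 of 778 (27 no longer passed, 37 reversed). One fit over 61 libraries left 698 of 699 and a fit of the contrasted groups alone 292 of 297.

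For genes, DESeq2 called 6641 in D2 MS against SS, 1 in D2 MM against MS and 9705 in D2 against D1 in SS. It called 5703 for the difference in MS against SS and 1 for that in MM. Limma voom called 3485 in D2 MS against SS, 1 in D1 MM against MS, 1 in the D1 interaction, 33 in D2 against D1, and 7 and 3 for the differences in MS and MM against SS. DESeq2 size factors in edgeR gave 8241 in D2 against D1. They moved the named genes by a median log2 of -0.28 there, -0.28 in D1 SM, -0.30 in D1 MS and -0.18 in D1 MM against SS, 0.31 in the D1 interaction, and 0.25, 0.31 and 0.22 in the differences for SM, MS and MM, so D1 values against SS hold relative to that shift. With 2 surrogate variables 42 genes were called in D2 against D1 (20 higher, 22 lower) and 1 in D2 MM against MS. With the background covariate 26 were called in D2 against D1 (14 higher, 12 lower) and 1 in D2 MM against MS, and with its filter 25 (14 higher, 11 lower) and 2. One fit over 61 libraries called 1 in the D1 interaction. The contrasted groups alone gave 11 in D2 against D1 (3 higher, 8 lower), where fewer libraries set the spread. Of the 20 genes of D2 against D1, those called again numbered 20 with DESeq2, 20 with its size factors, 17 with limma voom, 17 with surrogate variables, 16 with the covariate, 15 without D1 SS replicate 1 and 11 in the contrasted groups alone.

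With an estimated correlation, 0 lists were called in 14 comparisons and 1 in each of D2 MM against MS and D2 against D1. On simulated independent genes that test called the list raised 1.2-fold in D2 but not in D1 or across cell types. With the background covariate the count of lists was 4, 5, 6, 6 and 5 in D1 SM, MS against SS, MM against MS, MM against SM and the interaction. It was 11, 7 and 7 in D2 SM against SS, MM against MS and MM against SM, 8 in D2 against D1, and 3, 9 and 7 for the differences in SM, MS and MM. When D1 SS replicate 1 was left out it was 1 in D1 MS and 16 in D1 MM against SS, and 0 and 6 for the differences in SM and MM. The covariate with a filter gave no value for lists.

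List medians changed sign with the background covariate in D1 SM against SS for circadian clock (0.01), dopamine and cAMP signalling (0.1), glutamate receptor (0.04), GABA receptor (0.02), channel (0.06), synaptic vesicle (0.04), chromatin regulator (0.05) and oxidative phosphorylation genes (0.04). In D1 MS against SS they did so for heat shock (0.09), circadian (0.05), dopamine (0.11), glutamate (0.03), GABA (0.05), channel (0.05), vesicle (0.09), adhesion (0.03), chromatin (0.04), oxidative phosphorylation (0.08) and ribosomal protein genes (0.14). The others were adhesion genes in D1 MM against SS (0.02), GABA receptor genes in D1 MM against MS (-0.01), and glutamate (-0.01) and GABA receptor genes (-0.04) in the D1 interaction. In D2 MM against SM they were circadian (-0.01), channel (-0.01), chromatin (-0.01) and oxidative phosphorylation genes (-0.04) and D2 markers (-0.05), and in D2 against D1 glutamate receptor genes (0.01). For the difference in SM they were dopamine (-0.02) and glutamate genes (-0.02), and for that in MM dopamine (-0.04), channel (-0.02), vesicle (-0.06) and oxidative phosphorylation genes (-0.03).

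Leaving out D1 SS replicate 1 changed the sign in D1 SM against SS for immediate early (0.01), circadian (0.05), dopamine (0.14), glutamate (0.07), GABA (0.09), channel (0.12), vesicle (0.1), adhesion (0.07), chromatin (0.09) and oxidative phosphorylation genes (0.08). In D1 MS against SS it did so for heat shock (0.05), circadian (0.02), dopamine (0.07), glutamate (0.04), GABA (0.05), channel (0.04), vesicle (0.06), adhesion (0.03), chromatin (0.03), oxidative phosphorylation (0.06) and ribosomal protein genes (0.11), and in D1 MM against SS for adhesion genes (0.23). For the difference in SM the values were -0.05 for circadian, -0.1 for dopamine, -0.08 for glutamate, -0.1 for GABA, -0.1 for channel, -0.09 for vesicle, -0.06 for adhesion and -0.06 for chromatin genes. For that in MM they were -0.03 for circadian, -0.06 for dopamine, -0.09 for channel, -0.13 for vesicle, -0.04 for chromatin and -0.05 for oxidative phosphorylation genes and 0.03 for endothelial markers. The correlation of D1 with D2 changes in MM against SS moved from -0.31 to -0.61 among genes of at least 5 log2 CPM.

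The replicate numbers were also fitted as a replicate block. It called 8595 genes in D2 MS against SS (5844 higher, 2751 lower), 18 in D2 against D1 and 9 lists in D1 MM against SS (4 higher, 5 lower). Libraries of the same number correlated with r from -0.60 to 0.67, no comparison had every pair above 0.1, and at most 3 of 7 were closest to their own number. The closest to pairs were D2 MM and SM, with 6 of 7 above 0.1 (mean r = 0.25, against -0.04 for other numbers), and D1 SM and SS, with 5 of 8 (0.21 against -0.03). The numbers were therefore not taken to pair the libraries, and a call gained or lost under the block is not read as a change in the effect. On simulated data a 1.2-fold change was recovered for 2% of genes in D1 and 6% in D2. Depth was not varied, and variation shared across genes was left out.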
